A study of Homo sapiens with 4 samples.

How the data were processed

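Total RNA was extracted with TRIzol from 2 infected and 2 uninfected samples of H292 cells, amplified into biotinylated cRNA and hybridised to Illumina bead arrays, per the labels' protocols. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. The deposited probe table holds the raw intensity of each probe on a linear scale, per the file headers, with no background subtracted as the values show. It also holds a detection p-value for each probe and array, per the file headers, which is small where the probe is brighter than the array's negative controls. The authors also deposited quantile-normalized intensity values, once per probe in the series matrix and once per gene symbol in a table of 34600 symbols. The medians of the 4 matrix columns were 122.083, 122.067, 122.096 and 122.111, and each column ranked the probes as the raw array did (Spearman's rho 1), so these values are linear, are not centred and need no direction. How the authors formed 1 value per gene symbol is not given in the sources used here. A raw table per gene symbol repeats the same arrays and was not used. No per-sample column was left unmatched, and no slide or scan date is given in the sources used here, so no batch was tested.

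Starting from the raw probe intensities, the background was corrected with neqc of limma 3.58.1 in R 4.3.3, which fits normexp with negative controls inferred from the detection p-values, adds an offset of 16, quantile-normalizes the arrays and takes log2. A probe was tested if its detection p was under 0.05 on both arrays of at least 1 group, which left 19874 probes. Of the 47227 probes, 43957 carried a gene symbol and 3270 did not, and 589 tested probes without a symbol stayed out of the gene counts. Symbols were updated through a RefSeq table of assembly GRCh38.p14, used only for names and for the order of neighbouring genes. It named 27606 probes through their accession, 3386 through a current symbol and 1389 through a unique synonym, and 11576 kept the name in the file. For 4 tested genes, 1 of them called, the file's name had been turned into a date and was left as it was. A gene was represented by its tested probe with the highest mean log2 intensity, which gave 14480 genes, 3752 of them with more than 1 tested probe. No called gene had another probe called in the opposite direction, but the probes of a called gene did not all pass. With adjustment over probes, 1 of the 2 tested probes passed for CD74, TYMP, CA12, DKK3, HK2, CCN2, DSP, UHRF1, MCL1 and DKK1, among others. For BCL2, SLC29A1 and CANX, 0 of 2 passed. Probe sequences were not analysed here, so signal shared between similar transcripts was not removed.

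Infected and uninfected samples were compared with lmFit and eBayes of limma, two-sided, with all 4 arrays, no covariate and Benjamini-Hochberg adjustment over genes. A gene was called at an adjusted p under 0.05, and "rose" and "fell" refer to such calls. The fit had 2 residual degrees of freedom and 4.61 prior degrees of freedom, and the median SD of the log2 values between replicates was 0.140 in infected and 0.148 in uninfected samples. The test, the gene lists, the rule for the genes to be named and the alternatives were chosen before the data were examined. Of 43 gene lists, 40 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. Camera compares a list with the other genes. Camera with an estimated correlation, and fry, which tests whether a list moves on balance in 1 direction and makes no comparison with other genes, were alternatives. The genes of each list were also adjusted over the list alone. Some genes stand in more than 1 list: BIRC3 in those of NF-kB and apoptosis, BAX in those of p53 and apoptosis, NQO1 in those of NRF2 and the aryl hydrocarbon receptor, LOX in those of hypoxia and matrix, and BPIFA1 in those of antimicrobial proteins and mucins.

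The genes named are the 10 highest and 10 lowest fold changes among called genes above background on all 4 arrays. To these come the 5 highest and 5 lowest among called genes undetected on both arrays of 1 group, with names that are only LOC or open reading frame identifiers left out of both. To these come, from each list, up to 2 highest and 2 lowest called members, or the member with the smallest p where none was called. Called genes were eligible only if both infected arrays lay on the same side of both uninfected arrays. Other list members, such as IL1B, KRT14 or LCN2, were named after their values were seen. The values of a few single members of the lists are not reported here.

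The alternatives were no background correction, normexp without detection p-values at an offset of 50, median scaling, the authors' gene table and series matrix (with values under 10 set to 10 before log2), and a detection p under 0.01. Further alternatives were detection on all 4 arrays, no filter, the mean over a gene's probes, every probe counted, eBayes with trend and robust, the replicate number as a block, each array left out in turn and a fold of at least 2. The steps were tested on simulated arrays with 17406 tested genes. There, 0% of 49 genes changed 1.5-fold and 6.12% of 49 changed 2-fold were called in the right direction. For 3-fold it was 59.6% of 47 genes, for 4-fold 87.5% of 48, and 5 of 78 calls were false. Besides such genes only a single list was changed, whereas 4736 of the 14480 real genes had an unadjusted p under 0.05 in limma. Fewer changed genes make the adjusted threshold stricter, so these shares do not give the power of the real comparison. A simulated list raised 2-fold was found by camera with the preset correlation (adjusted p = 1.92e-27) and by fry (0.0214) but not with an estimated correlation (0.253). The noise of the simulated genes was drawn independently, so this does not show how the preset correlation serves for genes that vary together. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.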

Results

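Gene expression was measured with Illumina bead arrays in H292 cells, an established line that the labels describe as human non-small cell lung cancer. The cells either carried Mycoplasma hyorhinis, a bacterium without a cell wall that is a common contaminant of cell cultures, or had been freed of it. There were 2 infected and 2 uninfected samples with 1 array each. The uninfected cells were derived from the infected line by 2 weeks in medium with ciprofloxacin, an antibiotic that inhibits bacterial DNA gyrase. Both cultures were then grown for 4 weeks, or 12 passages, and tested by PCR for mycoplasma at each passage. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

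Each array reported 47227 probes. The median raw intensity was 122 and 117 on uninfected arrays 1 and 2, and 114 and 135 on infected arrays 1 and 2. A detection p under 0.05 was reached by 20245 and 20470 probes on the uninfected arrays and by 20650 and 21564 probes on the infected arrays. After background correction and quantile normalization, 14480 genes were above background on both arrays of at least 1 group. Across these genes, which are not independent replicates, Pearson's r of the log2 intensities was 0.988 between the uninfected arrays and 0.990 between the infected arrays. Between arrays of different groups it ranged from 0.959 to 0.967. The first principal component separated the groups and held 74.0% of the variance. With 2 arrays per group, the number of arrays limits the precision of every value.

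The comparison of infected with uninfected cells was made to address the effect of the mycoplasma on the expression of its host cells. Both uninfected samples had also had ciprofloxacin and separate culture, which cannot be told apart from the infection in any difference below. Infected cells had more RNA of some interferon-induced genes: IFI6 was 24.8-fold higher (log2 change 4.63 ± 0.26, SE, n = 2 per group) and MX1, an antiviral GTPase, was 16.6-fold higher (4.06 ± 0.39). The complement component C3 was 18.3-fold higher (4.19 ± 0.18, and 2.00 in the authors' gene table). S100A8, a subunit of the antimicrobial protein calprotectin, was 12.1-fold higher (3.59 ± 0.57). Its call ended with trend and robust variance (limma, adjusted p = 0.0734). KRT13, a keratin of stratified epithelia, was 14.7-fold lower (-3.88 ± 0.29, and -2.57 without background correction), and THBS1, a secreted matrix glycoprotein, was 9.97-fold lower (-3.32 ± 0.31). IL1R2, a decoy receptor for interleukin 1, was 8.13-fold lower (-3.02 ± 0.18), with a log2 change of -0.85 in the authors' gene table. All values after ± are moderated standard errors of the log2 change from eBayes unless stated otherwise, and all changes are infected minus uninfected. Moderation draws each gene's variance toward a value shared by all genes. These errors therefore do not show the spread between a gene's own replicates, which for S100A8 had an SD of 1.13 in infected and 0.84 in uninfected samples.

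**Figure D1:**
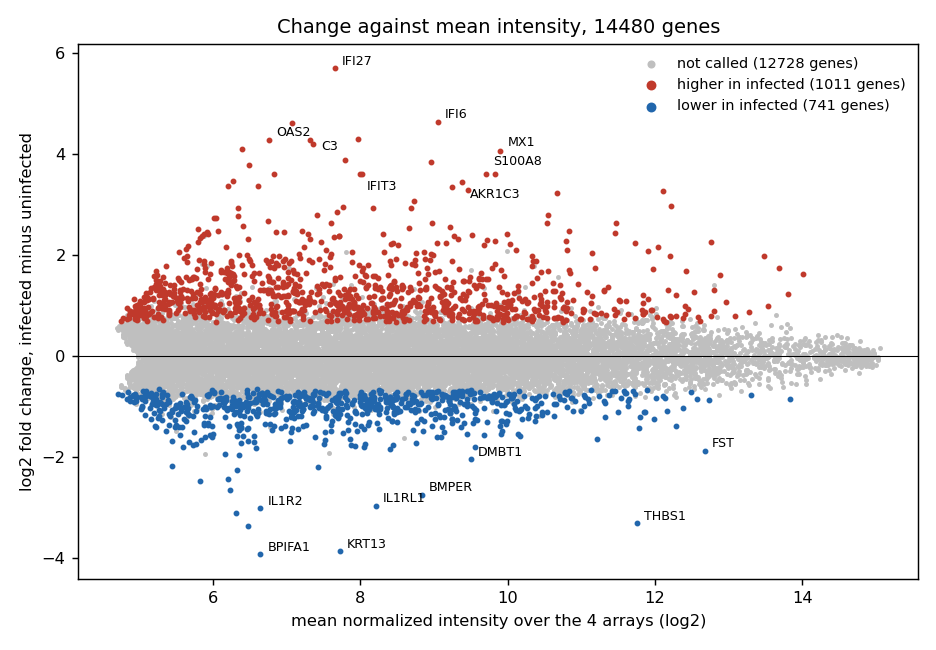
Log2 fold change (infected minus uninfected, vertical axis) against the mean normalized log2 intensity over the 4 arrays (horizontal axis), with 1 point per tested gene. The 1011 genes that rose are red, the 741 that fell are blue and the others are grey, and IFI27 and IFI6 lie farthest above 0 among the labelled genes while BPIFA1 and KRT13 lie farthest below it.

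The remaining genes among the 10 largest rises above background on all 4 arrays were IFI44 at 14.8-fold, ISG15 at 14.3-fold, FBXO32 at 12.2-fold, IFIT3 at 12.1-fold, AKR1C4 at 12.1-fold and AKR1C3 at 10.9-fold. The log2 change of IFIT3, 3.60 here, was 2.06 in the authors' gene table, and that of FBXO32, 3.61 here, was 1.86 in that table. For IFIT3 it was 2.26 without infected replicate 1, in a fit that chose the probe of each gene anew. IFIT3 has 3 tested probes, and the probe used here had 9.44 on infected array 2 against a mean of 6.20 on the uninfected arrays. That lower value therefore need not come from the replicate left out. ISG15 is a ubiquitin-like modifier, FBXO32 is the substrate-binding subunit of a ubiquitin ligase, and the AKR1C enzymes reduce steroids and reactive carbonyls. Adjusted p in limma lay between 0.000954 (C3) and 0.0163 (S100A8) for these 10 genes. The 10 largest falls above background on all 4 arrays, besides those of KRT13, THBS1 and IL1R2, were as follows. IL1RL1, the receptor of interleukin 33, fell 7.81-fold and BMPER, a secreted protein that binds bone morphogenetic proteins, 6.76-fold. SPRY4, an inhibitor of receptor tyrosine kinase signalling, fell 4.59-fold (log2 change -2.20, and -0.66 in the authors' gene table), DMBT1, a mucosal scavenger receptor, 4.15-fold, and ADAMTS6, a metalloprotease, 3.91-fold. ZNF365 fell 3.84-fold and FST, which binds activins, 3.69-fold. The log2 change of IL1RL1 was -2.97 here and -1.44 in the authors' gene table, and without background correction ADAMTS6 had -0.89 instead of -1.97 and ZNF365 -0.84 instead of -1.94. Adjusted p for these 10 genes lay between 0.00140 (IL1R2) and 0.0122 (SPRY4). Of the tested probes of IL1R2, 2 of 3 fell past the threshold, and of those of SPRY4, 1 of 2.

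**Figure D2:**
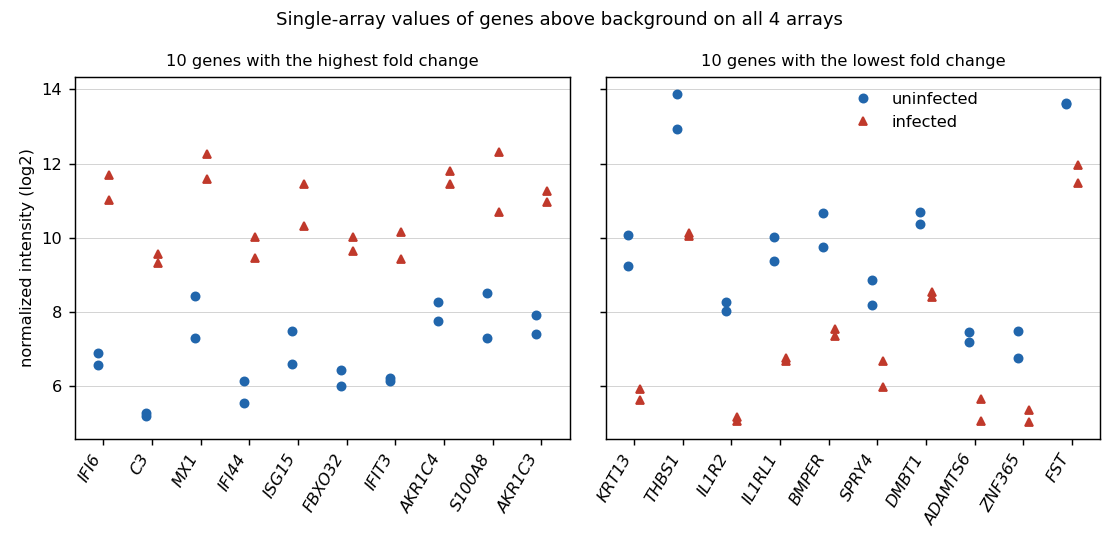
Normalized log2 intensity (vertical axis) of the 10 genes with the highest and the 10 with the lowest fold changes among named genes above background on all 4 arrays, with 1 symbol per array (circles for 2 uninfected, triangles for 2 infected arrays). By the rule for naming genes, both arrays of a group lie on the same side of both arrays of the other group.

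Genes that were above background in only 1 of the groups have a fold that is a lower bound. It sets the mean of the bright group against the mean, in the dim group, of the lowest detected signal of each array or the gene's own signal where that was higher. The bounds depend on the background correction: without it the log2 change was 3.65 instead of 5.70 for IFI27 and 2.30 instead of 4.28 for OAS2, which had 1.21 in the authors' gene table. With the correction used, IFI27 was at least 44.7-fold higher in infected cells (adjusted p = 0.000866), OAS2 at least 14.7-fold, IFI44L at least 10.7-fold and OASL at least 9.73-fold. OAS2 and OASL belong to the oligoadenylate synthetase family of antiviral proteins, and 3 of the 4 tested probes of OAS2 rose. PLAAT4, a phospholipase and acyltransferase, was at least 7.92-fold higher. In the other direction, BPIFA1, a secreted defence protein of the airways, was at least 12.6-fold lower (adjusted p = 0.0174). Its 2 uninfected arrays differed, at 7.51 and 9.72, and the log2 change of -3.93 was -2.83 without uninfected replicate 2 and -2.11 without background correction. The keratin KRT4 was at least 4.31-fold lower, the cyclin CCNA1 at least 3.00-fold, KRTAP2-4 at least 2.90-fold and the transcription factor KLF15 at least 2.62-fold. KRTAP2-4 has near-identical neighbouring copies, so its value is uncertain as to which copy was measured.

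In limma, 1752 genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 1011 were higher and 741 were lower in infected cells. A change of at least 2-fold was reached by 613 of the higher and 334 of the lower genes. For all 1752 genes both infected arrays lay on the same side of both uninfected arrays, which a call nearly requires. The same held for 63.3% of the tested genes. By chance it holds for a single gene with a probability of 33.3%, but genes on the same 4 arrays are not independent. Leaving out 1 array left 690 genes without uninfected replicate 1, 328 without uninfected replicate 2 and 80 without infected replicate 2. Without infected replicate 1 limma called 0 genes, with 3660 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0837. In these fits the lone sample is assumed to vary like the other group. No named gene that changed turned its sign in any of them.

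Genes induced by interferons formed the group with the most members that rose. Of the 35 tested interferon-stimulated genes 25 rose, none fell and 10 did not pass the test; adjusted over the list alone, 29 rose. The median log2 change was 1.91, also with 7 members at their bound, and the list was higher than the other genes in camera (adjusted p = 1.84e-21, and adjusted p = 0.361 with an estimated correlation). Beside the genes named above, IFIT1 (3.28 ± 0.40), OAS1 (2.93 ± 0.22) and IRF9 (2.41 ± 0.18), a transcription factor of interferon signalling, rose. In the list of MHC class I antigen presentation 5 of 17 tested genes rose, none fell and 12 did not pass; adjusted over the list alone, 12 rose. Those 5 were HLA-B (2.06 ± 0.25), the immunoproteasome subunits PSMB9 (1.91 ± 0.18) and PSMB8 (1.13 ± 0.16), the peptide transporter TAP1 (1.11 ± 0.19) and the proteasome activator PSME1 (0.79 ± 0.17). The list had a median of 0.55 and an adjusted p of 3.31e-06 in camera, with adjusted p = 0.320 with an estimated correlation. HLA class I transcripts are similar in sequence, and 1 of the 2 PSMB9 probes rose. Of 3 tested genes of MHC class II antigen presentation, too few for a list test, HLA-DMA (1.55 ± 0.19) and CD74 (1.02 ± 0.17) rose, also adjusted over the list alone. HLA-DRA had a change of -0.21, and the median was 1.02.

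Among 19 tested NF-kB target genes 10 rose, none fell and 9 did not pass; adjusted over the list alone, 14 rose. SOD2, the mitochondrial superoxide dismutase, rose by 2.28 ± 0.18 and the transcription factor IRF1 by 2.24 ± 0.20, and NFKBIA, the inhibitor of NF-kB, by 1.73 ± 0.21. The list's median was 0.78 (camera adjusted p = 1.39e-07, and adjusted p = 0.320 with an estimated correlation). Of 20 tested cytokines and chemokines 12 rose, none fell and 8 did not pass; adjusted over the list alone, 15 rose. IL6, above background on 1 of the uninfected arrays, had the largest change (4.27 ± 0.66, limma adjusted p = 0.0154). The size of this change is uncertain, with 2.62 at its lowest over the settings that kept all arrays. The chemokine CCL20 (2.95 ± 0.18), IL1B (2.64 ± 0.40) and CXCL8 (1.65 ± 0.32) rose too. The median was 1.29, or 0.89 with 6 members at their bound, and 0.51 without background correction. Camera gave an adjusted p of 6.33e-09, and adjusted p = 0.320 with an estimated correlation.

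Antimicrobial and acute-phase proteins had a median of 2.42, or 2.38 with 4 members at their bound and 1.47 without background correction. Of 15 tested genes 11 rose, 2 fell and 2 did not pass, and 12 rose and 2 fell adjusted over the list alone (camera adjusted p = 6.41e-08, and adjusted p = 0.351 with an estimated correlation). S100A9 (3.26 ± 0.27), the partner of S100A8, the acute-phase protein SAA1 (2.79 ± 0.17), complement factor CFB (2.42 ± 0.24) and LCN2 (1.74 ± 0.17), which binds bacterial siderophores, rose. The 2 genes that fell, BPIFA1 and BPIFB1 (-1.66 ± 0.20, above background on 1 of the infected arrays, and -0.63 without background correction), encode related secreted airway proteins. With no filter on dim probes the list's median was 0.70. Of 20 tested Toll-like receptor and inflammasome components 6 rose, none fell and 14 did not pass; adjusted over the list alone, 7 rose. LY96, the co-receptor of Toll-like receptor 4, rose by 2.63 ± 0.19 and the receptor-associated kinase IRAK2 by 2.26 ± 0.23, and CD14, PYCARD, CASP1 and TLR3 were the other members that rose. The list had a median of 0.09, with a range over settings that kept all arrays from 0.03 to 0.29, and an adjusted p of 0.0305 in camera, with adjusted p = 0.361 with an estimated correlation. This call ended with the mean over a gene's probes (adjusted p = 0.0622) and without infected replicate 1 (adjusted p = 0.0838), in a range over all alternatives from 0.000743 to 0.361.

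The lists of oxidative stress, xenobiotic metabolism, lysosome and hypoxia genes were higher than the other genes in camera with its preset correlation. Among 25 tested NRF2 and oxidative stress genes 11 rose, none fell and 14 did not pass; adjusted over the list alone, 16 rose (median 0.65, camera adjusted p = 3.24e-08, and adjusted p = 0.320 with an estimated correlation). AKR1C3 (3.44 ± 0.23) and AKR1C2 (3.23 ± 0.24) had the largest changes, and the AKR1C genes are so similar that their values are not independent measurements. HMOX1, which degrades heme and was above background on 1 of the uninfected arrays, rose by 2.93 ± 0.34 and FTH1, the ferritin heavy chain, by 2.48 ± 0.17. Of 14 tested aryl hydrocarbon receptor and xenobiotic genes 6 rose, none fell and 8 did not pass; adjusted over the list alone, 10 rose. The list's median was 0.82, or 0.65 with 2 members at their bound, and 0.41 without background correction (camera adjusted p = 1.44e-05, and adjusted p = 0.361 with an estimated correlation). CYP1B1, a monooxygenase induced by the receptor, rose by 2.85 ± 0.26 and CYP1A1 was at least 1.29-fold higher. CYP24A1 (2.58 ± 0.46), above background on 1 of the uninfected arrays, degrades vitamin D and is known as a target of the vitamin D receptor. Of 24 tested autophagy and lysosome genes 9 rose, none fell and 15 did not pass; adjusted over the list alone, 13 rose. GABARAPL1, an autophagosome protein, rose by 2.22 ± 0.30, and the cathepsins CTSZ and CTSB by 1.79 ± 0.25 and 1.42 ± 0.17. The median was 0.63 (camera adjusted p = 1.76e-06, and adjusted p = 0.320 with an estimated correlation). Of 18 tested hypoxia-inducible genes 5 rose, none fell and 13 did not pass, and 5 rose adjusted over the list alone. They were the carbonic anhydrases CA9 (at least 3.90-fold) and CA12 (2.00 ± 0.20, and 0.69 in the authors' gene table), the collagen cross-linking enzyme LOX (at least 2.35-fold), NDRG1 (1.53 ± 0.22) and P4HA2 (0.89 ± 0.19). Both bounds hold only with the correction used. Over the settings that kept all arrays the lowest log2 change was 0.93 for CA9 and 0.65 for LOX. The list's median was 0.47 (camera adjusted p = 0.000125, and adjusted p = 0.320 with an estimated correlation).

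**Figure D3:**
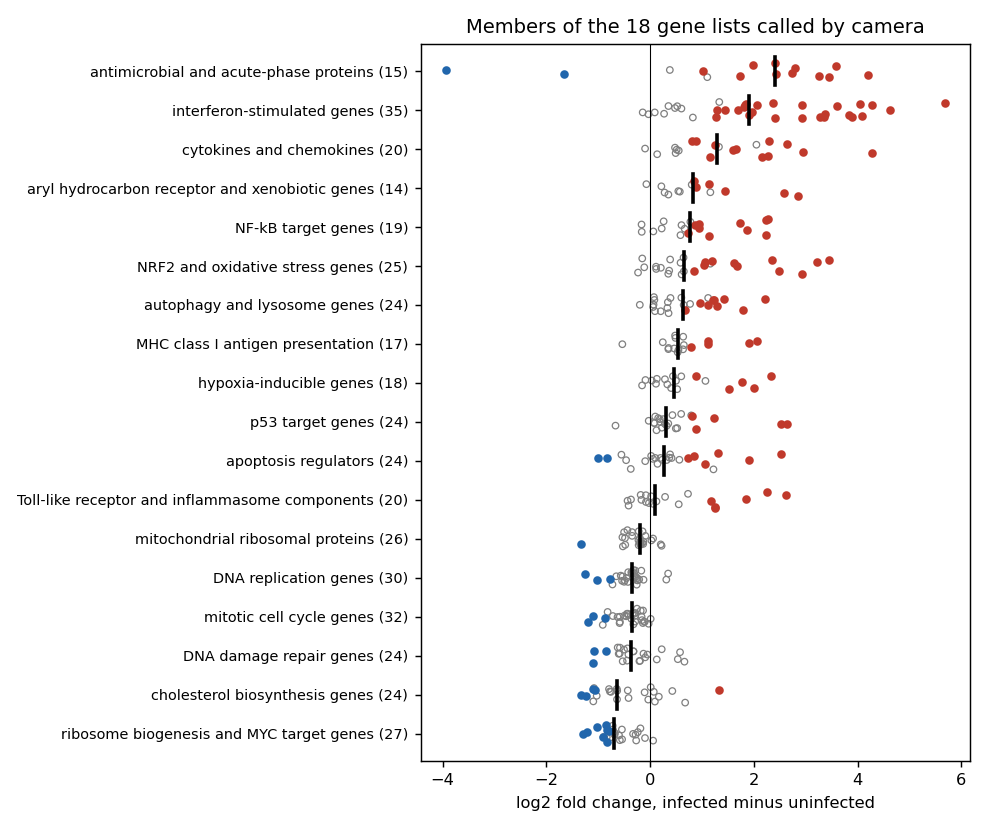
Log2 fold change (infected minus uninfected, horizontal axis) of the tested members of the 18 gene lists that differed from the other genes in camera, with the number of tested members in parentheses. Red points rose and blue points fell in limma, open points did not pass, and black bars are the list medians, which run from 2.42 for antimicrobial and acute-phase proteins to -0.70 for ribosome biogenesis and MYC target genes.

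Of 24 tested p53 target genes 5 rose, none fell and 19 did not pass, and 5 rose adjusted over the list alone (median 0.30, or 0.19 in the authors' gene table, camera adjusted p = 0.000398, and adjusted p = 0.351 with an estimated correlation). They were GDF15 (2.64 ± 0.24), a stress-induced cytokine, the pore-forming BAX (2.53 ± 0.51, and 1.65 without uninfected replicate 2), the p53 ubiquitin ligase MDM2 (1.24 ± 0.18), the cell-cycle inhibitor CDKN1A (0.88 ± 0.18) and SPATA18 (0.81 ± 0.19). Of 24 tested apoptosis regulators 6 rose, 2 fell and 16 did not pass; adjusted over the list alone, 7 rose and 2 fell. Besides BAX, the initiator caspase CASP8 rose (1.91 ± 0.29, and 0.50 in the authors' gene table), and MCL1 (-0.83 ± 0.19) and BCL2 (-1.0 ± 0.24), which oppose cell death, fell. The calls of the last 2 were not stable: MCL1 had a change of -0.54 with the mean over a gene's probes (adjusted p = 0.0831), and BCL2 lost its call in 7 of 12 settings that kept all arrays, with -0.22 in the authors' gene table (adjusted p = 0.185). Their median was 0.28, or 0.17 with the mean over a gene's probes (camera adjusted p = 0.0451, and adjusted p = 0.611 with an estimated correlation). This call ended with genes above background on all 4 arrays (adjusted p = 0.0551), with fry (0.108), without infected replicate 1 (0.221) and without infected replicate 2 (0.0771), in a range from 0.00466 to 0.611.

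The lists of proliferation genes were lower in infected cells, while few of their members fell. Of 32 tested mitotic cell cycle genes 3 fell, none rose and 29 did not pass; adjusted over the list alone, 6 fell. MKI67, a marker of cycling cells, fell by 1.19 ± 0.17 on the log2 scale, the spindle protein TPX2 by 1.10 ± 0.25 and BUB1B by 0.88 ± 0.17. The median of -0.35 was below that of the other genes in camera (adjusted p = 3.16e-05, and adjusted p = 0.450 with an estimated correlation). Of 30 tested DNA replication genes 3 fell, none rose and 27 did not pass, and 3 fell adjusted over the list alone. UHRF1 (-1.25 ± 0.22), CDC6 (-1.02 ± 0.17) and POLA1 (-0.78 ± 0.18) fell, and the list's median was -0.34 (camera adjusted p = 0.000145, and adjusted p = 0.450 with an estimated correlation). The median was -0.53 without uninfected replicate 1 and -0.22 without uninfected replicate 2, and UHRF1 had a change of -0.52 with the mean over a gene's probes. Both calls ended with fry, at adjusted p = 0.0771 for the mitotic and 0.0850 for the replication list, in ranges from 1.81e-08 to 0.450 and from 2.99e-07 to 0.450. Of 24 tested DNA damage repair genes 3 fell, none rose and 21 did not pass; adjusted over the list alone, 4 fell and 1 rose. RAD54L (-1.07 ± 0.21), the helicase BLM (-1.09 ± 0.25) and H2AX (-0.86 ± 0.17) fell, with a list median of -0.37, or -0.23 in the authors' gene table (camera adjusted p = 0.0391, and adjusted p = 0.361 with an estimated correlation). Without uninfected replicate 1 the adjusted p of this list was 0.124 and without uninfected replicate 2 it was 0.0793, in a range from 0.00379 to 0.361.

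Ribosome biogenesis and MYC target genes had the lowest median of the lists tested, -0.70. Of 27 tested genes 8 fell, none rose and 19 did not pass; adjusted over the list alone, 19 fell (camera adjusted p = 1.39e-07, and adjusted p = 0.351 with an estimated correlation). RRP12, a ribosomal RNA processing factor, fell by 1.30 ± 0.17 on the log2 scale, and ODC1 and SRM, enzymes of polyamine synthesis, by 1.21 ± 0.27 and 1.03 ± 0.21. MYC itself had a change of -0.27 and did not pass (adjusted p = 0.329). Of 26 tested mitochondrial ribosomal proteins and related genes 1 fell, none rose and 25 did not pass, and 1 fell adjusted over the list alone. That gene, TWNK (-1.32 ± 0.17), encodes the helicase of mitochondrial DNA and not a ribosomal protein. The list's median was -0.19 (camera adjusted p = 0.0148, and adjusted p = 0.468 with an estimated correlation), and its call ended with fry (0.0734) and without uninfected replicate 1 (0.142), in a range from 0.000468 to 0.468. Of 24 tested cholesterol biosynthesis genes 4 fell, 1 rose and 19 did not pass; adjusted over the list alone, 13 fell and 2 rose. The squalene epoxidase SQLE (-1.23 ± 0.20) was among those that fell, and the sterol reductase TM7SF2 rose by 1.33 ± 0.23. The median was -0.64 (camera adjusted p = 0.00792, and adjusted p = 0.611 with an estimated correlation). The call ended with fry (0.207) and without uninfected replicate 2 (0.116), in a range from 0.000569 to 0.611, and the median was -0.41 without infected replicate 2 and -0.38 without background correction.

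The other lists did not differ from the remaining genes in camera, although single members changed. Among 24 tested keratins and squamous differentiation genes 5 fell, 1 rose and 18 did not pass; adjusted over the list alone, 5 fell and 2 rose. KRT13 and KRT4 fell most, KRT14 (-1.75 ± 0.16, above background on 1 of the infected arrays), KRT6A (-1.39 ± 0.17) and KRT16 (-1.21 ± 0.21) fell too, and CNFN rose by 0.70 ± 0.17. CNFN lost its call in 7 of 12 settings that kept all arrays, among them median scaling (adjusted p = 0.156), and its change was 0.38 without background correction. The list's median was 0.04 and its mean -0.34, and camera gave the direction of the mean (adjusted p = 0.50). With median scaling it was called lower (adjusted p = 0.0148), in a range from 0.0148 to 0.968. Of 11 tested mucins and airway secretory genes 2 rose, 1 fell and 8 did not pass; adjusted over the list alone, 2 rose and 3 fell. CLCA2 (2.01 ± 0.35) and GCNT3 (1.22 ± 0.24) rose, and BPIFA1 fell. The median of 0.22 and the mean of -0.25 differed in sign, and the test followed the mean (adjusted p = 0.944). Of 18 tested epithelial junction genes 1 rose, 3 fell and 14 did not pass; adjusted over the list alone, 3 rose and 3 fell (median 0.06, adjusted p = 0.758). The desmosomal protein DSP (-1.28 ± 0.23), the epithelial transcription factor GRHL2 (-1.28 ± 0.23) and TJP1 (-1.03 ± 0.21) fell, and TJP3 rose by 1.62 ± 0.35. TJP3 was above background on 1 of the uninfected arrays, so the size of its rise is uncertain, and it was 0.65 without background correction. Of 18 tested integrins and adhesion receptors 1 fell, ITGA6 (-0.81 ± 0.18), and 17 did not pass and 0 passed adjusted over the list alone (median 0.09, adjusted p = 0.716).

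Matrix genes moved in both directions. Of 22 tested extracellular matrix and mesenchymal genes 5 rose, 3 fell and 14 did not pass, with the same counts adjusted over the list alone. ACTA2 (1.64 ± 0.17), the smooth muscle actin, and LOX rose, and THBS1 and CCN2 (-1.61 ± 0.19), a secreted matricellular protein, fell. The median and the mean were both -0.03, whereas camera ranked the list higher (adjusted p = 0.716). Of 17 tested matrix metalloproteinases, members of the plasminogen system and inhibitors 2 rose, 1 fell and 14 did not pass; adjusted over the list alone, 8 rose and 2 fell. The collagenase MMP1 (1.76 ± 0.29) and MMP14 (1.05 ± 0.24) rose and ADAMTS1 (-1.76 ± 0.24) fell. MMP14 was above background on 1 of the uninfected arrays, and without background correction its change was 0.35 (adjusted p = 0.0903), 1 of 6 settings with all arrays that ended its call. This list's median was 0.53 (adjusted p = 0.0520), or 0.35 without background correction and 0.16 with no filter on dim probes, and it was called higher in 8 alternatives that keep all arrays and without uninfected replicate 2 (0.0303), in a range from 0.0155 to 0.50. Of 19 tested genes of TGF-beta and BMP signalling 3 rose, 3 fell and 13 did not pass; adjusted over the list alone, 4 rose and 4 fell. BAMBI (1.49 ± 0.22), ID3 (1.31 ± 0.19) and ID1 (0.98 ± 0.21) rose, while FST, INHBB (-1.64 ± 0.21) and BMP7 (at least 1.78-fold lower) fell. The mean of -0.03 and the test, which ranked the list higher, differed in sign (adjusted p = 0.953). Of 15 tested Wnt pathway genes 2 rose, 2 fell and 11 did not pass; adjusted over the list alone, 2 rose and 3 fell (median -0.27, or 0.05 without infected replicate 2, adjusted p = 0.332). WNT10A (1.40 ± 0.21) and DKK3 (1.00 ± 0.22) rose, and PORCN (-0.83 ± 0.17) and DKK1 (-0.78 ± 0.17) fell. Of 24 tested immediate-early and AP-1 genes 1 rose, JUNB (0.97 ± 0.23), 1 fell, SPRY4, and 22 did not pass; adjusted over the list alone, 2 rose and 5 fell. Their median was -0.18 (adjusted p = 0.404), and the list was called lower with every probe counted (0.0465), in a range from 0.0465 to 0.859. Of 11 tested genes of the EGFR family and its ligands 2 fell, NRG1 (-1.66 ± 0.19) and LRIG1 (-0.77 ± 0.17), and 9 did not pass; adjusted over the list alone, 3 fell and 1 rose (median -0.18, adjusted p = 0.409).

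The other lists of metabolism and those of protein stress were not called either. Of 35 tested genes of nucleotide and nucleoside metabolism 3 rose, 2 fell and 30 did not pass, with the same counts adjusted over the list alone. The pyrimidine-degrading enzymes CDA (1.40 ± 0.21) and TYMP (1.36 ± 0.20) and ADA (1.23 ± 0.18) rose. CAD, which starts pyrimidine synthesis, fell by 1.06 ± 0.20 on the log2 scale and the nucleoside transporter SLC29A1 by 0.92 ± 0.22. The median was -0.27 (adjusted p = 0.139), and the list was called lower without infected replicate 1 (0.0160), in a range from 0.0160 to 0.611. Of 30 tested amino acid response genes 6 rose, 1 fell and 23 did not pass; adjusted over the list alone, 7 rose and 2 fell. NUPR1 (1.38 ± 0.30) and CEBPB (1.07 ± 0.19) rose and STC2 (-0.73 ± 0.18, and adjusted p = 0.180 with median scaling) fell, with a list median of 0.19, or 0.13 with 1 member at its bound, and 0.07 at its lowest over the alternatives (adjusted p = 0.142). Of 22 tested glycolysis genes 2 rose, PFKFB4 (1.18 ± 0.23) and ALDOC (0.95 ± 0.18), 1 fell, the hexokinase HK2 (-1.28 ± 0.19), and 19 did not pass, with the same counts adjusted over the list alone (median 0.17, adjusted p = 0.311). Fry called these last 2 lists higher, at adjusted p = 0.0462 and 0.0200, in ranges from 0.0462 to 0.450 and from 0.0200 to 0.718. Of 20 tested unfolded protein response genes 1 rose, DNAJB9 (0.85 ± 0.18), 2 fell, HYOU1 (-1.32 ± 0.23) and CANX (-0.85 ± 0.20), and 17 did not pass; adjusted over the list alone, 2 rose and 4 fell (median -0.04, adjusted p = 0.876). Of 15 tested heat shock proteins CRYAB (1.57 ± 0.33) and HSPB1 (0.98 ± 0.21) rose and 13 did not pass, with the same 2 genes' count adjusted over the list alone. The median of -0.15 and the mean of 0.04 differed in sign (adjusted p = 0.804). Of 19 tested fatty acid synthesis genes 1 fell, the desaturase SCD (-1.66 ± 0.22), and 18 did not pass; adjusted over the list alone, 5 fell and 2 rose (median -0.02, adjusted p = 0.599).

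No member passed the test in 5 of the lists tested with camera. The member with the smallest p was MTF1 (-0.56 ± 0.17, adjusted p = 0.0734) among 10 tested metallothioneins and zinc transporters and SDHA (-0.58 ± 0.18, adjusted p = 0.0774) among 31 tested oxidative phosphorylation genes. It was RPS23 (-0.77 ± 0.21, adjusted p = 0.0610) among 36 tested cytosolic ribosomal proteins, PSMD3 (-0.50 ± 0.20, adjusted p = 0.134) among 27 tested proteasome subunits and B2M (0.64 ± 0.17, adjusted p = 0.0539) among 18 tested housekeeping genes. In these 5 lists 0 genes passed adjusted over the list alone. Their medians were -0.18, -0.02, -0.05, -0.06 and -0.14 in that order, with camera adjusted p of 0.363, 0.859, 0.574, 0.574 and 0.444.

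Markers of other cell types were mostly below background. On both infected arrays 4 of 16 leukocyte, 4 of 14 fibroblast and 2 of 12 endothelial markers were detected, against 5, 3 and 1 on both uninfected arrays. Of 5 tested leukocyte markers CD68 (1.20 ± 0.17), a lysosomal protein that is not limited to leukocytes, rose, CD2 (-0.88 ± 0.19) fell and 3 did not pass, with the same counts adjusted over the list alone (median 0.10, camera adjusted p = 0.599). Of the 3 tested probes of CD68, 1 rose past the threshold. CD2 was above background on 1 of the infected arrays and had a change of -0.28 without background correction (adjusted p = 0.137). Of 4 tested fibroblast markers FAP (1.52 ± 0.25) rose, MFAP5 (-1.59 ± 0.18) fell and 2 did not pass; adjusted over the list alone, 2 rose and 1 fell, with a median of 0.67. Neither of the 2 tested endothelial markers passed, with CDH5 at 0.71 ± 0.24 (adjusted p = 0.0973) and a median of 0.47, and 1 rose adjusted over the list alone. The last 2 lists had too few tested members for a list test.

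Among the 40 lists tested, camera with its preset correlation called 12 higher and 6 lower. With an estimated correlation camera called 0 of the 40, with 6 at an unadjusted p under 0.05, and fry called 13 of the 18. Of the 108 named genes that changed, 73 kept their call in the settings that kept all arrays and tested them, with the replicate block and the minimum fold left aside. The other 35, among them BPIFA1, S100A8, BAX, CYP24A1, UHRF1, CDC6, MCL1, BCL2, MMP14, CNFN, CD2, CANX, SLC29A1, STC2, DKK1, DKK3, ITGA6, JUNB, LRIG1, PORCN, BLM, DNAJB9, HSPB1, TPX2, TJP3, GRHL2 and DSP, lost it in at least 1 setting, 32 of them with no filter on dim probes. The log2 change of 58 of the 114 named genes moved by over 1.5 times in a setting that kept all arrays. For 38 of these 58 the fit reported here gave the largest or nearly the largest size, so the folds given are mostly at the upper end of their range. C3, above background on all 4 arrays, had a log2 change of 4.19 here and 2.00 in the authors' gene table. The medians of the lists of fatty acid synthesis, EGFR family, matrix, keratin, mucin, integrin and TGF-beta genes changed sign in at least 1 such setting. Those of the unfolded protein response, immediate-early, epithelial junction, Wnt, oxidative phosphorylation and leukocyte lists changed sign with 1 array left out.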

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

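Only the settings run on gene families were chosen after the data were seen. Against 1752 called genes (1011 higher, 741 lower), the lower genes numbered 1207 without background correction, 1252 with normexp alone, 1217 from the series matrix and 1352 with trend and robust variance, which called 2811 in all. Median scaling called 1072 genes, 311 of them lower, so 71.0% of calls were higher against 57.7%, and its fit gave all genes 1 shared variance. With no filter, which tests more genes, 809 were called (538 higher, 271 lower), and at least 2-fold changes numbered 947 (613 and 334). No protocol says that the replicate numbers pair the samples. The deviations of same-numbered arrays correlated at -0.085 over genes, which cannot exclude a pairing. The replicate block, with 1230 calls and 453 lower, changed the call of 13 named genes. Without 1 array 0 to 690 genes were called, 0 to 450 higher and 0 to 240 lower, from fewer samples. Of the 1752 genes, 1445 were also called without background correction, 961 with median scaling, 1452 from the series matrix, 1675 with trend and robust variance and 809 with no filter. Camera with an estimated correlation called 0 lists (0 higher, 0 lower, and 6 at an unadjusted p under 0.05) against 18 (12 and 6), and fry called 2 lower. The cause was not tested. A simulated list was also missed with an estimated correlation. The simulated genes varied independently, so the simulation cannot decide between the preset and the estimated correlation. The median size of the called changes was 1.03 here and 0.70 without background correction. No named gene or list turned its direction past a threshold.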

Other observations

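All tests in this part were chosen after the result was seen, except the test of neighbouring genes. Gene families were formed from the letters that open a symbol, and 152 families of at least 10 tested genes were tested for called genes with Fisher's exact test, one-sided, in 304 tests adjusted together. Fisher's exact test counts genes as independent, but all genes were measured on the same arrays. Its p-values therefore do not measure the spread between samples, and they can be too small where the genes of a family vary together. Of 12080 background genes 7.61% rose and 5.28% fell. The SNORD family is named for small nucleolar RNAs that mostly guide the methylation of ribosomal RNA and mostly lie in introns of host genes. Its genes fell more often than that background, with 13 of 58 lower and 1 higher (Fisher's exact test, adjusted p = 0.00233). SNORD80 (log2 change -1.38 ± 0.23, SE, n = 2 per group) and SNORD96A (-1.34 ± 0.19) were among them, SNORD13 rose (1.88 ± 0.24, above background on 1 of the uninfected arrays), and the family's median was -0.58, or -0.24 without background correction. Median scaling called 6 of them lower, no filter 7, and the fits without 1 array 0 to 1. For the related SNORA family 7 of 53 genes were lower (Fisher's exact test, adjusted p = 0.539). Probe sequences were not analysed here, so whether these probes read the small RNAs or the transcripts of their host genes stays open.

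Interleukins and their receptors rose more often than the background, with 11 of 41 higher and 4 lower (Fisher's exact test, adjusted p = 0.0267). This p-value also treats genes on the same arrays as independent and can be too small. Members outside the fixed lists that rose included IL10RB (2.04 ± 0.30), a receptor subunit shared by several cytokines, IL15 (1.49 ± 0.26) and IL27RA (1.45 ± 0.24). IL13RA2, IL16, IL20RB and IL23A rose too. The 4 lower genes were all receptors: IL1R2, IL1RL1, IL20RA (-0.98 ± 0.24) and IL18R1 (-0.89 ± 0.19). With genes detected on all 4 arrays 7 were higher, with no filter 6, and without 1 array 0 to 6. Keratins had 7 of 30 genes lower, which did not pass (Fisher's exact test, adjusted p = 0.0788). Single genes outside the lists also differed, among them the retinol dehydrogenase DHRS9 (4.61 ± 0.37) and the antiviral factor TRIM22 (2.19 ± 0.22), which rose, and the imprinted transcript H19 (-2.66 ± 0.51) and the gastrokine GKN2 (-3.37 ± 0.55), which fell. DHRS9 was above background on 1 of the uninfected arrays, and H19 and GKN2 each on 1 of the infected arrays.

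The rise of the interferon-stimulated genes was weighed against 3 explanations. A difference in array brightness is argued against. The infected arrays were the dimmest and the brightest, yet the lowest of the 4 raw infected-minus-uninfected list medians was 1.22 on the log2 scale. Within a group the raw list medians were -0.18 (uninfected 1 minus uninfected 2) and -0.32 (infected 1 minus infected 2). After normalization, which evens out brightness, the lowest of the 4 was 1.65, against 0.42 at most within a group. RNA from leukocytes as the whole cause is argued against too, since 4 of 16 leukocyte markers were above background on both infected arrays and 5 on both uninfected arrays, with AIF1 (5.85 against 5.88) and LAPTM5 (5.51 against 5.41) close to background in both groups by their mean log2 intensity. CD68 rose by 1.20 ± 0.17, but it is a lysosomal protein that is not limited to leukocytes. The ciprofloxacin treatment and separate culture of the uninfected cells cannot be told apart from the infection, because 0 arrays hold infected cells treated with ciprofloxacin. The hypothesis that the infection itself keeps these genes high may hold, and it stays open with that one.

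The rise of the AKR1C genes could come from probes that read the transcript of a single paralog. For the NRF2 list this is argued against as the whole cause: without its 3 AKR members the list kept a median log2 change of 0.65, with 9 of 22 genes higher and none lower. Whether AKR1C2, AKR1C3 and AKR1C4 each rose stays open, since probe sequences were not analysed here, and the antibiotic and the separate culture are open here as well.

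The 1752 calls could also reflect copy-number differences that arose between the cultures. A gain from 2 to 3 copies shifts genes by 0.58 on the log2 scale, and over 229 windows of 50 neighbouring genes (12106 genes) the largest window median had a size of 0.30, against 0.43 in 100 shuffled orders. This argues against gains from 2 to 3 copies that fill a window as the whole cause. The windows were fixed and did not overlap, so a gain lying across the border of 2 windows could be missed. Simulated 1.5-fold changes were fitted at 0.796 of their true log2 size, and the starting copy number was not measured here. The SD of the window medians was 0.0994 against at most 0.0951 in shuffled orders, so smaller shared shifts of neighbouring genes and narrower changes stay open. Of the 3 balanced splits of the arrays, 1 gave 1752 genes, the real one, and the highest other gave 0 (84 at an unadjusted p under 0.05), and 3 splits are too few for a share under 0.05.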
